A study of Mus musculus with 10 samples.

How the data were processed

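The deposited data were a single table for the series, holding RPKM (reads scaled to gene length and library total) for 32830 genes in each of 10 libraries, with the chromosome, start, end, strand and length of every gene. Per the labels' protocols, total RNA was taken from tumour tissue with TRIzol and made into stranded mRNA libraries for paired-end sequencing on an Illumina instrument. The labels name 2 library kits without saying which was used for which sample. Per the submitters' processing notes the genome build was GRCm38 (mm10). The aligner, the counting program, the annotation release and whether counting used strand are not given in the sources used here, so values of antisense and overlapping genes, and of near-identical copies such as Ifit3 and Ifit3b or the immunoglobulin light chain, kallikrein and class I genes, are uncertain.

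In the deposited RPKM values, each value multiplied by the gene's length was a whole multiple of what 1 read is worth in its library, within a tolerance of 1e-06, for 100% of the values in every library. Whole reads and library totals were recovered in this way. The totals were 25132208 and 34677434 reads for PBS replicates 1 and 2, 27030157, 25188785 and 28781315 reads for the inhibitor, 31519039 and 34230298 reads for the antibody, and 29586539, 33619415 and 36260856 reads for the combination. The 10 genes with most reads took from 4.39% to 17.8% of a library, the highest share in antibody replicate 1. Of the gene names, 95.5% were found in GENCODE M21 for GRCm38, and 99.96% of those overlapped their GENCODE span. Coordinates are given on GRCm38, 1-based.

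Samples were grouped by the treatment label, and the combination by the sample titles, because the treatment text of combination replicates 2 and 3 carries different antibody numbers. Column names were matched to sample titles by group word and number, allowing for spelling differences between them. Replicate pairs were compared before averaging, and each of the 8 pairs differed by far more than sampling noise (chi-square per gene from 23.9 to 532).

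Because the unit was RPKM, the test was limma (version 3.58.1, R 4.3.3) on log2(RPKM + 0.5), for the 19368 genes at an RPKM of at least 0.5 in at least 2 samples. A model of 4 group means was fitted to all 10 samples (6 residual degrees of freedom), with a mean-variance trend, robust empirical Bayes moderation and Benjamini-Hochberg adjustment at 0.05 within each of 7 contrasts. A log2 fold change is on the log2(RPKM + 0.5) scale and so understates the change of low genes. Values beside a gene are means ± SD over the replicates of a group. The design fixed beforehand named a count test for a table of counts. It was not used here, since the unit is RPKM, and limma with voom on the recovered reads (21143 genes with at least 10 reads in at least 2 samples) was added after the data were seen.

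The samples, the tests, 42 gene lists and the rule for naming genes were fixed before the data were examined. Lists with at least 3 tested genes were tested with limma's camera on the same values, with an inter-gene correlation preset at 0.01 and adjustment over the lists within a contrast. Beside it stand camera with an estimated correlation and fry, which called 0 lists in every contrast. Of 566 list genes named, 556 were in the table. Genes were named by rule: up to 10 per direction past the threshold with a mean of at least 1 RPKM in the higher group, otherwise the 5 with the lowest p per direction as not passing, 36 fixed genes, and up to 4 members with the lowest p of each list discussed. Noncoding and pseudogene entries among the 5 are mostly left unnamed in the text. List levels were also compared by an exact two-sided permutation test within antibody strata. Figures were drawn with matplotlib 3.10.9.

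On simulated reads with 4-fold changes in about 200 genes, the test recovered 86.2% of them for the inhibitor against PBS, 85.0% for the antibody against PBS, 85.6% for the combination against PBS, 91.3% for the combination against the antibody, 89.3% for the combination against the inhibitor and 99.0% for the averaged inhibitor effect. With each gene's own spread in these libraries the recovered shares were 66.0%, 55.0%, 61.5%, 65.5%, 71.5% and 80.5% of 200 genes. A list shifted by 2 log2 units was called in each of 7 contrasts with 0 of 41 other simulated lists. That result does not give the rate of false list calls in these libraries, where genes of a list can move together. Across the 100 arrangements of the inhibitor labels within antibody strata, a median of 14 lists was called for the averaged inhibitor effect.

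Alternatives were pseudocounts of 0.1 and 1, no filter and a filter at 1 RPKM, median-ratio scaling, quantile normalization, limma without trend, only the groups compared, the replicate number as a block, and leaving out each sample. Added after the data were seen were voom with and without sample quality weights, the muscle list level as a covariate, the muscle and pancreas levels as covariates, and leaving out the 3 libraries with over 5% of reads in the muscle list. The median log2 fold change over all genes was −0.20 for the inhibitor, −0.17 for the antibody and −0.05 for the combination against PBS, 0.12 for the combination against the antibody, 0.15 against the inhibitor and 0.33 for the interaction, and list medians are to be read against these values. With median-ratio scaling these medians lay between −0.01 and 0.02.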

Results

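RNA was sequenced from tumours of a mouse ovarian cancer model after treatment with PBS, with an inhibitor of the cyclin-dependent kinases CDK4 and CDK6 (CDK4/6i), with an antibody against the checkpoint receptor PD-1, or with both agents. The labels give 2 PBS, 3 CDK4/6i, 2 PD-1 antibody and 3 combination samples, 10 in all. The series asks whether the inhibitor adds to the antibody through tertiary lymphoid structures, which are organised B and T cell aggregates within tissue. Totals ran from 25132208 reads (PBS replicate 1) to 36260856 reads (combination replicate 3). Nothing in the labels ties replicates to separate animals beyond the word mice, so p-values measure the spread between these samples.

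The libraries differed most in transcripts of tissues that can border a tumour. The 12 skeletal muscle genes took 10.45% of the reads of inhibitor replicate 1 (95% Clopper-Pearson interval 10.44% to 10.46%), 9.23% of inhibitor replicate 2 (9.22% to 9.24%) and 10.2% of combination replicate 1 (10.19% to 10.21%), against 0.0016% of inhibitor replicate 3 (0.00146% to 0.00175%). These intervals cover counting error only, since PCR reads are not independent molecules. Genes of the exocrine pancreas, such as the digestive proteases Prss2 and Cela3b, took 7.14% (7.13% to 7.15%) and 2.94% (2.93% to 2.94%) of the reads of the antibody libraries and at most 1.10% (1.10% to 1.11%) of any other. Liver transcripts took 0.638% (0.635% to 0.641%) of the reads of PBS replicate 2, where Alb, which encodes serum albumin, stood at 1395 RPKM, and 0.0733% (0.0724% to 0.0742%) of antibody replicate 2. Adipocyte transcripts were highest in PBS replicate 1, at 0.472% (0.469% to 0.474%) of its reads. The median correlation across genes was 0.911 for the 8 pairs of libraries within groups and 0.904 for the 37 pairs between groups, so libraries of 1 group resembled each other little more than libraries of different groups. The first principal component held 48.8% of the variance, of which 31.9% lay between groups.

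**Figure D1:**
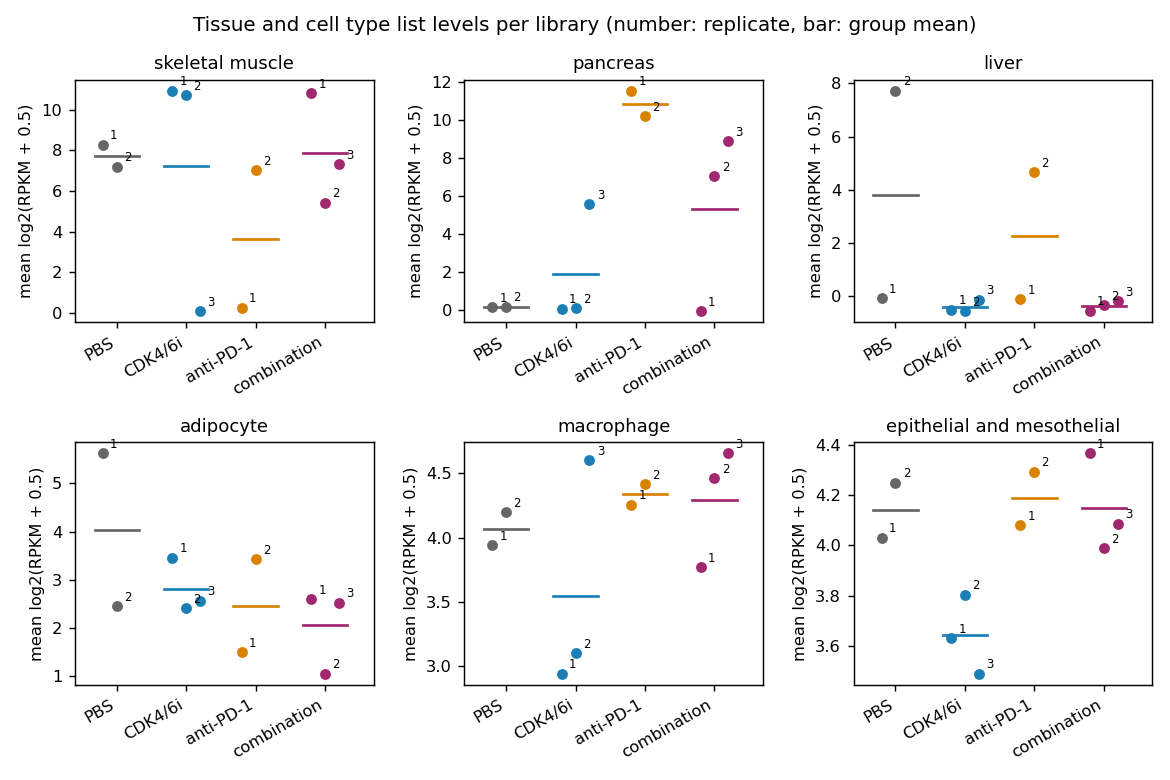
Mean log2(RPKM + 0.5) of 6 tissue and cell type lists in each library, with the 4 treatment groups on the x axis, 1 point per library numbered by replicate and a bar at the group mean. The skeletal muscle list ranged from 0.09 to 10.93 within the inhibitor group, and the pancreas list stood at 11.54 and 10.19 in the antibody libraries.

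The first comparison asks what the inhibitor alone changed relative to PBS. Transcripts of lipid synthesis and of antibody-producing plasma cells stood lower in the inhibitor tumours, and those of hypoxia stood higher. Those of inflammatory secretion and interferon were called higher too, but not without inhibitor replicate 3. Genes of T cells, B cells and DNA replication were not called. By camera, 10 of the 42 lists were called here, and none with an estimated correlation (smallest adjusted p = 0.875). Genes of fatty acid and sterol synthesis were lower in the inhibitor tumours for 19 of the 20 tested members (median log2 fold change −0.52, camera adjusted p = 0.00773), and 3 members passed when adjusted over the list alone. Scd1, the desaturase that makes monounsaturated fatty acids (chromosome 19, 44394451 to 44407709), stood at 101 ± 4.4 RPKM in PBS (SD, n = 2) and 21.02 ± 11 RPKM with the inhibitor (SD, n = 3), a log2 fold change of −2.42 (SE 0.63). Fasn, which encodes fatty acid synthase, differed by −1.18 (SE 0.31) and Thrsp, a lipogenesis regulator, by −3.10 (SE 0.87). Adipocyte transcripts in PBS replicate 1 and liver transcripts in PBS replicate 2 moved with this list, and all 9 liver genes were lower with the inhibitor (median −4.50, camera adjusted p = 0.00113). Leaving out 1 PBS or antibody library leaves a lone sample in that group, which is assumed to vary like the others. Without PBS replicate 2 neither list was called, with a median of −0.09 for fatty acid and sterol genes (adjusted p = 0.767) and an adjusted p of 0.476 for liver genes, and the test turned to the other side for both. The fatty acid call was also lost without inhibitor replicate 2 (adjusted p = 0.0842) and with the muscle and pancreas covariates (median −0.61, adjusted p = 0.0522). The liver call was lost without inhibitor replicate 3 (adjusted p = 0.169), with voom (adjusted p = 0.479), with sample quality weights (adjusted p = 0.719) and with these covariates (adjusted p = 0.101). Immunoglobulin and plasma cell genes were lower for 15 of 17 members (median −1.37, camera adjusted p = 0.00113). Among them, Jchain, the joining chain of secreted IgM and IgA, differed by −1.94 (SE 0.59) and the light chain constant gene Iglc2 by −2.10 (SE 0.42), the latter in a family of near-identical copies. The plasma cell call was lost without PBS replicate 2 (median −0.76, adjusted p = 0.133). Leaving out the 3 libraries rich in muscle transcripts keeps inhibitor replicate 3 as the lone inhibitor sample, with its spread taken from other groups. In that fit plasma cell genes (median −0.47, adjusted p = 0.288), fatty acid and sterol genes (median −0.18, adjusted p = 0.603) and liver genes (median −4.45, adjusted p = 0.0925) were not called.

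Several lists stood higher with the inhibitor alone. Hypoxia and glycolysis genes were higher for 14 of 16 members (median 0.30, camera adjusted p = 3.77e-08), with Pgk1, a glycolytic kinase, at a log2 fold change of 0.66 (SE 0.32). The list level was highest in inhibitor replicate 3, at 5.17, against 4.58 and 4.34 in replicates 1 and 2 and 4.27 and 4.22 in PBS. Senescence-associated secreted factors were higher for 15 of 17 members (median 1.05, camera adjusted p = 1.65e-06), yet this rested on inhibitor replicate 3. In that library the neutrophil attractant Cxcl1 stood at 519 RPKM, against 8.68 and 6.31 RPKM in its group mates, and without it the list median was −0.19 (adjusted p = 0.628). Type I interferon genes were higher for 19 of 22 members (median 0.19, camera adjusted p = 6.90e-06), but the median was −0.24 without inhibitor replicate 3 (adjusted p = 0.455), −0.15 without PBS replicate 1 (adjusted p = 0.254) and −0.20 with sample quality weights (adjusted p = 0.288). Chemokines of the tertiary lymphoid structure signature, which recruit lymphocytes, were higher for 8 of 9 members (median 0.30, camera adjusted p = 0.00544), with a median of −0.43 without inhibitor replicate 3 (adjusted p = 0.628) and of 0.42 without PBS replicate 1 (adjusted p = 0.154). This call was also lost with median-ratio scaling (median 0.53, adjusted p = 0.145), with quantile normalization (median 0.49, adjusted p = 0.156) and without a filter (median 0.24, adjusted p = 0.0577). With sample quality weights (median −0.31, adjusted p = 0.183) and with muscle and pancreas covariates (median −0.084, adjusted p = 0.0756) the median fell below 0 and the call was lost. At the level of single genes limma called 0 of 19368, with 1036 at an unadjusted p under 0.05 against 968.4 by chance, and voom on the recovered reads called 0, with 1102 unadjusted. The lowest p values fell to Aldh1l1, a folate enzyme (13.0 ± 4.4 against 1.41 ± 0.33 RPKM, limma adjusted p = 0.135), and to Cat, which encodes catalase (67.3 ± 10 against 21.5 ± 1.1 RPKM, limma adjusted p = 0.162). Leaving out PBS replicate 1, which left the library with liver transcripts as the only PBS sample, gave a gene count of 117, 115 of them lower with the inhibitor. With inhibitor replicate 3 as the lone inhibitor sample, without the 3 muscle-rich libraries, the count was 37.

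The second comparison asks what the PD-1 antibody alone changed. Genes of T cells and their cytotoxic subset, of checkpoint receptors, which restrain T cells, and of B cells stood higher in the antibody tumours. Transcripts of the exocrine pancreas stood higher as well, and lipid synthesis genes lower. Camera called 24 lists, and none kept its call with an estimated correlation (smallest adjusted p = 0.470). T cell genes were higher for 17 of 18 members (median log2 fold change 1.05, camera adjusted p = 1.61e-09) and genes of CD8 and cytotoxic cells for 15 of 15 (median 0.98, camera adjusted p = 8.38e-09). Cd8a, the alpha chain of the CD8 co-receptor, stood at 3.02 ± 1.4 RPKM with the antibody and 0.706 ± 0.023 RPKM in PBS (SD, n = 2 each), a log2 fold change of 1.48 (SE 0.66, limma adjusted p = 0.58). Cd8b1 differed by 1.87 (SE 0.78), the T cell receptor complex gene Cd3d by 1.14 (SE 0.59), and Pdcd1, which encodes PD-1 itself, by 1.60 (SE 0.99). Immune checkpoint genes were higher for 13 of 14 members (median 0.68, camera adjusted p = 8.25e-06), interferon gamma response genes for 18 of 19 (median 0.65, camera adjusted p = 3.85e-05) and B cell genes for 15 of 16 (median 0.61, camera adjusted p = 3.88e-04), with Cd79b, a signalling chain of the B cell receptor, at 0.95 (SE 0.86). Without antibody replicate 1, which leaves a lone antibody sample, the interferon gamma (median 0.27) and B cell calls (median 0.30) were lost. The lymphoid structure chemokines were higher for 6 of 9 members (median 0.72, camera adjusted p = 0.00422), a call lost without antibody replicate 1 (median 0.38). All 20 fatty acid and sterol genes were lower (median −0.39, camera adjusted p = 0.0188), Scd1 by −2.20 (SE 0.69), but without PBS replicate 2 the median was 0.0067 (adjusted p = 0.813). The call was lost without the muscle-rich libraries (median −0.39, adjusted p = 0.0558) and with the muscle and pancreas covariates (median −1.04, adjusted p = 0.0989). With the muscle level as a covariate, the B cell (median −0.025, adjusted p = 0.150), interferon gamma (median 0.019, adjusted p = 0.0765) and lymphoid structure chemokine lists (median 0.011, adjusted p = 0.155) were not called.

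Pancreas transcripts moved with the antibody group: all 9 tested pancreas genes were higher (median 10.92, camera adjusted p = 6.30e-19), and each passed when adjusted over the list alone. The kallikrein gene Klk1b11, a member of a family of similar copies, had the lowest p of all genes (limma adjusted p = 0.0588), at 8.29 ± 1.3 RPKM with the antibody and 0 reads in PBS. Taking 3 reads over the PBS group as the limit of that 0, or 0.0581 RPKM, it was at least 142.6-fold higher, a bound for counting error only. limma called 0 genes, with 1675 unadjusted, and voom called 0, with 1574 unadjusted. The count was 39 without combination replicate 1, 5 without antibody replicate 1, 6 without combination replicate 3, 50 without the 3 muscle-rich libraries, and 66 when only the PBS and antibody libraries were fitted. With muscle and pancreas levels as covariates, the T cell list turned to a median of −1.17 and the CD8 list to −1.20. The B cell (−1.73), interferon gamma (−1.38), checkpoint (−1.35) and lymphoid structure chemokine lists (−1.33) turned as well. The pancreas level itself was 11.54 and 10.19 with the antibody and 0.14 and 0.17 in PBS. Adjusting for it removes much of the contrast, so these turns cannot decide whether the lists follow the antibody.

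The third comparison sets the combination against PBS. Interferon response genes, which cells switch on against viruses, stood higher in the combination tumours. So did genes of antigen presentation, T cells, checkpoints and lymphocyte-recruiting chemokines, while stress-response, fat and liver transcripts stood lower. For most of the immune lists the rise came from combination replicates 2 and 3. By camera, 25 of the 42 lists were called here, and none with an estimated correlation (smallest adjusted p = 0.343). All 22 type I interferon response genes were higher in the combination tumours (median log2 fold change 1.43, camera adjusted p = 8.28e-20), as were all 19 interferon gamma response genes (median 1.36, camera adjusted p = 2.21e-15). Irf7, the transcription factor that amplifies interferon production (chromosome 7, 141262706 to 141266481), stood at 8.93 ± 3.5 RPKM in PBS (SD, n = 2) and 44.3 ± 18 RPKM in the combination (SD, n = 3), a log2 fold change of 2.21 (SE 0.66) that did not pass on its own. Bst2, a membrane protein that tethers budding viruses, differed by 1.41 (SE 0.38), the antiviral nucleotide synthetase Oas1a by 1.58 (SE 0.49), Zbp1, a sensor of nucleic acids, by 2.05 (SE 0.73), and the interferon-induced GTPase Gbp3 by 1.47 (SE 0.47). Genes of MHC class I presentation were higher for 16 of 16 members (median 0.78, camera adjusted p = 2.70e-13) and those of MHC class II for 11 of 11 (median 0.65, camera adjusted p = 2.17e-08), with the class I gene H2-T23 at 1.09 (SE 0.37) and the class II loading gene H2-DMb2 at 1.23 (SE 0.39). All 18 T cell genes (median 0.98, camera adjusted p = 1.92e-11) and all 15 CD8 and cytotoxic genes (median 0.95, camera adjusted p = 2.70e-13) were higher, Cd8a by 1.64 (SE 0.60) and Cd3e, a chain of the T cell receptor complex, by 1.41 (SE 0.62). Checkpoint genes were higher for 12 of 14 members (median 0.82, camera adjusted p = 1.01e-05), with Cd274, which encodes the PD-1 ligand, at 9.85 ± 7.1 RPKM in PBS and 38.7 ± 27 RPKM in the combination. With the muscle and pancreas levels as covariates, T cell (median −0.0015, adjusted p = 0.152), MHC class II (median 0.064, adjusted p = 0.152) and checkpoint genes (median −0.093, adjusted p = 0.540) were not called. Combination replicate 1, rich in muscle transcripts, lay below PBS replicate 2 in the interferon gamma, class I, class II, T cell, CD8 and checkpoint lists. T cell levels were 1.09, 2.80 and 2.88 in combination replicates 1 to 3, against 1.08 and 1.48 in PBS.

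For the theme in the series title, 8 of 9 tested chemokines of the tertiary lymphoid structure signature were higher in the combination than in PBS (median 1.44, camera adjusted p = 1.22e-06), and 1, Ccl8, passed when adjusted over the list alone. Ccl8, which draws monocytes and T cells, stood at 10.2 ± 1.3 RPKM in PBS and 35.99 ± 11 RPKM in the combination (log2 fold change 1.72, SE 0.32, limma adjusted p = 0.619). The interferon-induced chemokines Cxcl9 and Cxcl10 differed by 1.52 (SE 0.79) and 1.44 (SE 0.68), and Ccl3 by 1.65 (SE 0.94). Cxcl13, the attractant of B cells to follicles, stood at 4.93 ± 3.0 RPKM in PBS and 4.56 ± 1.9 RPKM in the combination, and at 16.1 ± 25 RPKM in the inhibitor group, where a single library carried it. Ccl19 was below the expression filter. Receptors and cytokines of lymphoid organisation were higher for 16 of 19 members (median 0.49, camera adjusted p = 1.76e-05), though not with the muscle and pancreas covariates (median −0.21, adjusted p = 0.499). B cell genes were higher for 14 of 16 members (median 0.56, camera adjusted p = 0.00317), with Cd22, an inhibitory receptor of B cells, at 0.84 (SE 0.89) and the B cell surface gene Ms4a1 at 0.61 (SE 0.64). The B cell list was not called without PBS replicate 1 (median 0.33), without combination replicate 2 (median 0.084, adjusted p = 0.271) or with the muscle and pancreas covariates (median −0.37, adjusted p = 0.436). In combination replicate 1 the B cell level was −0.30, against 0.33 and 0.74 in PBS. The lymphoid organisation level there was 1.20 against 1.30 and 1.55, while the chemokine level was 2.49 against 2.00 and 2.29.

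Other lists stood lower in the combination than in PBS. Immediate early and heat shock genes were lower for 13 of 13 members (median −1.13, camera adjusted p = 5.08e-05), with the chaperone Hspa1b at −2.51 (SE 0.98), but without PBS replicate 1 the median turned to 0.43. The muscle and pancreas covariates ended the call (median −0.66, adjusted p = 0.925). Fatty acid and sterol genes were lower for 16 of 20 (median −0.26, camera adjusted p = 4.25e-04), Scd1 by −2.75 (SE 0.63), and turned to a median of 0.14 without PBS replicate 2. E2F targets were called as higher (22 of 30, median 0.07, camera adjusted p = 0.0382), but turned to a median of −0.078 without PBS replicate 1, and were not called without combination replicate 2 (adjusted p = 0.227) or 3 (adjusted p = 0.232). With all libraries of both groups kept, the E2F call was lost without a filter (adjusted p = 0.0832), when only the 2 groups were fitted (adjusted p = 0.0512) and with the muscle covariate (adjusted p = 0.0849). It turned with the muscle and pancreas covariates (median −0.20). Liver (9 of 9, median −4.14) and adipocyte genes (11 of 11, median −2.04) were lower beside them, the former not without PBS replicate 2 (adjusted p = 0.968) and the latter not without PBS replicate 1 (adjusted p = 0.759), and pancreas genes higher (9 of 9, median 5.40). limma called 0 genes, with 686 unadjusted, and voom called 0, with 642 unadjusted. Aldh1l1 (limma adjusted p = 0.180), Ces1f, a carboxylesterase (limma adjusted p = 0.362), and Cat (limma adjusted p = 0.362) had the lowest p on the lower side and Clic5, an intracellular chloride channel gene, on the higher side (log2 fold change 1.07, SE 0.18, limma adjusted p = 0.601). For the genes on the lower side, a source in the fat or liver tissue of the PBS libraries was not tested. The count of genes was 94 without PBS replicate 1 and 1 without inhibitor replicate 3.

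**Figure D2:**
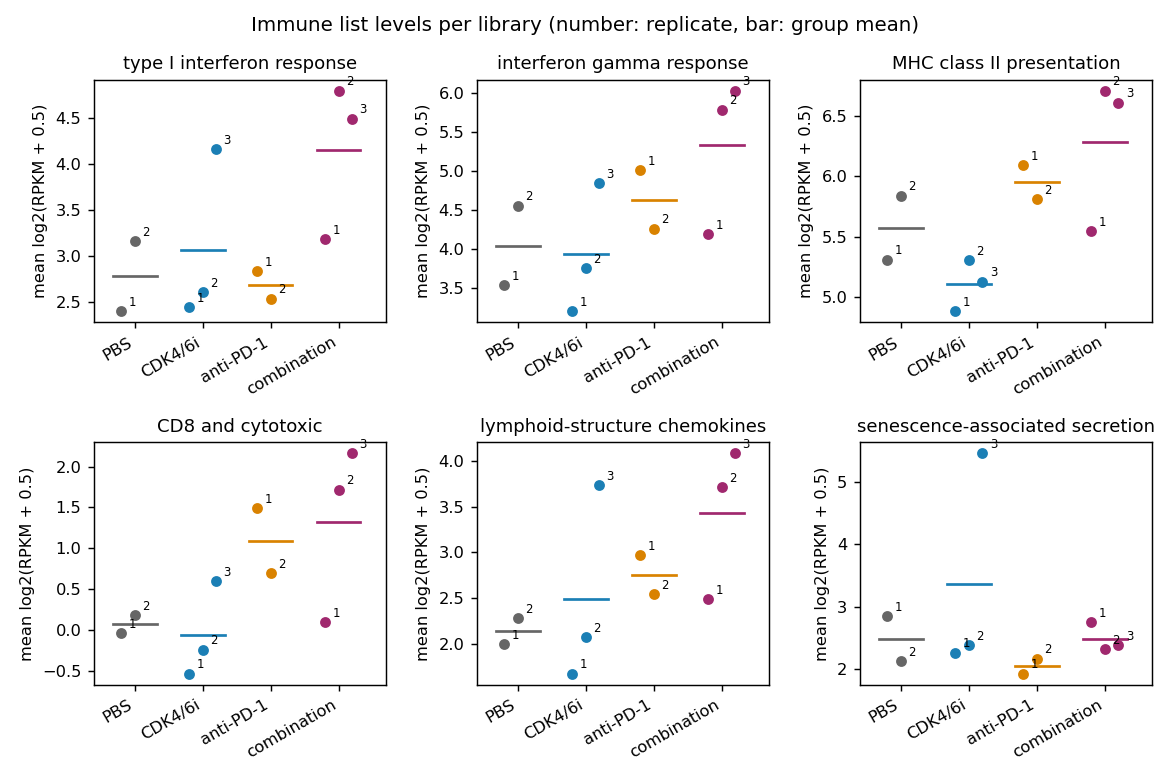
Mean log2(RPKM + 0.5) of 6 immune lists in each library, by treatment group on the x axis, 1 point per library numbered by replicate and a bar at the group mean. The type I interferon list stood at 4.80 and 4.49 in combination replicates 2 and 3, against 2.41 and 3.17 in PBS, and combination replicate 1 lay at 3.18.

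The fourth comparison, the combination against the antibody alone, is the one the series is named for. Interferon response genes and the class I presentation genes that they induce stood higher in the combination. Genes of T cells, cytotoxic cells, B cells and lymphoid chemokines were not called. Camera called 12 lists, and none kept its call with an estimated correlation (smallest adjusted p = 0.639). Type I interferon response genes were higher in the combination for all 22 members (median log2 fold change 1.502, camera adjusted p = 2.56e-11). Isg15, the ubiquitin-like modifier induced by interferon (chromosome 4, 156199424 to 156200818), stood at 12.3 ± 1.7 RPKM with the antibody (SD, n = 2) and 51.5 ± 25 RPKM in the combination (SD, n = 3), a log2 fold change of 1.91 (SE 0.55). Ifit3, an interferon-induced antiviral gene with the near-identical copy Ifit3b, differed by 2.19 (SE 0.73), Irf7 by 2.25 (SE 0.66), Bst2 by 1.41 (SE 0.38) and Oas1a by 1.49 (SE 0.49). Genes of MHC class I presentation were higher for 15 of 16 members (median 0.56, camera adjusted p = 9.56e-05), with the peptide loading gene Tapbp at 0.64 (SE 0.19), and interferon gamma response genes for all 19 (median 0.72, camera adjusted p = 0.0169), with Gbp3 at 1.19 (SE 0.47). The interferon gamma call was lost when only the 2 groups were fitted (adjusted p = 0.0519) and without combination replicate 2 (adjusted p = 0.120) or replicate 3 (adjusted p = 0.287), and its test turned without antibody replicate 2 (median 0.38, adjusted p = 0.962).

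Lymphocyte lists were not called for the combination against the antibody alone. T cell genes were higher for 13 of 18 members (median 0.11, camera adjusted p = 0.601), CD8 and cytotoxic genes for 13 of 15 (median 0.15, camera adjusted p = 0.956) and B cell genes for 5 of 16 (median −0.02, camera adjusted p = 0.212). The lymphoid structure chemokines were higher for 8 of 9 members without passing (median 0.84, camera adjusted p = 0.268). Combination replicate 1, with 10.2% of its reads in the muscle list, was lowest of its group. T cell levels were 1.09, 2.80 and 2.88 in combination replicates 1 to 3, against 2.43 and 1.94 with the antibody. CD8 levels were 0.09, 1.72 and 2.16 against 1.49 and 0.69, and B cell levels −0.30, 1.96 and 1.42 against 1.31 and 0.86. Only lists called in the main fit were followed through the alternatives, so these were not. Mitosis genes were called as lower (17 of 26, median −0.057, camera adjusted p = 0.00854), which did not hold without antibody replicate 1 (adjusted p = 0.270) or combination replicate 1 (median 0.047, adjusted p = 0.102). It was also lost without a filter (adjusted p = 0.0674), with sample quality weights (median 0.051, adjusted p = 0.149), with muscle and pancreas covariates (median 0.17, adjusted p = 0.110) and without the muscle-rich libraries (median 0.047, adjusted p = 0.0763). Pancreas genes (9 of 9, median −5.53) and liver genes (9 of 9, median −2.45) were lower in the combination, the liver genes not past the threshold without antibody replicate 2 (adjusted p = 0.118). limma called 0 genes, with 1075 unadjusted, and voom called 0, with 1079 unadjusted. Ifi35, an interferon-induced gene, had the lowest p on the higher side (12.2 ± 0.66 against 22.8 ± 3.2 RPKM, log2 fold change 0.87, SE 0.16, limma adjusted p = 0.455) and Klk1b11 on the lower side (limma adjusted p = 0.120). Leaving out antibody replicate 1 gave 6 genes, leaving out combination replicate 3 gave 4 and leaving out inhibitor replicate 3 gave 1. With sample quality weights voom called 100.

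The fifth comparison asks what the antibody added to the inhibitor. Genes of class II presentation, by which myeloid and B cells show antigen to helper T cells, stood higher in the combination, with genes of T cells, dendritic cells and B cells. Genes of hypoxia and of the immediate early response to stress stood lower. By camera, 23 of the 42 lists were called here, and none with an estimated correlation (smallest adjusted p = 0.352). All 11 genes of MHC class II presentation were higher in the combination (median log2 fold change 1.09, camera adjusted p = 9.38e-09), 10 of them past the threshold when adjusted over the list alone. Ciita, the master regulator of class II genes (chromosome 16, 10488178 to 10527564), stood at 4.52 ± 1.4 RPKM with the inhibitor and 20 ± 9.7 RPKM in the combination (SD, n = 3 each), a log2 fold change of 1.92 (SE 0.53), and H2-Ab1, a class II beta chain, differed by 1.26 (SE 0.25). Interferon gamma response genes were higher for 18 of 19 members (median 1.59, camera adjusted p = 1.11e-08), 14 of them when adjusted over the list alone. T cell genes were higher for 18 of 18 (median 1.38, camera adjusted p = 1.15e-08), with Cd3g at 2.12 (SE 0.55) and the T cell kinase Lck at 1.88 (SE 0.65), and CD8 and cytotoxic genes for 15 of 15 (median 1.25, camera adjusted p = 8.86e-08), 4 of them when adjusted over the list alone, with Cd8a at 2.06 (SE 0.54). Dendritic cell genes were higher for 12 of 13 (median 0.73, camera adjusted p = 3.51e-04), 5 when adjusted over the list alone, among them Batf3 (1.01, SE 0.25) and Clec9a (1.42, SE 0.37), which mark cross-presenting dendritic cells. B cell genes were higher for 15 of 16 (median 1.05, camera adjusted p = 0.00809), with Cd79a at 1.74 (SE 0.71), a call lost without inhibitor replicate 1 (adjusted p = 0.0598) or combination replicate 2 (adjusted p = 0.190).

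Immediate early and heat shock genes were lower in the combination for 13 of 13 members (median −1.78, camera adjusted p = 4.57e-10), with the transcription factor Junb at −1.81 (SE 0.62) and Hspa1b at −2.56 (SE 0.88). Within each group this list was highest in the libraries rich in muscle transcripts. It stood at 5.35 and 5.04 in inhibitor replicates 1 and 2, which are rich in them, and at 3.89 in replicate 3. In the combination it stood at 4.19 in the muscle-rich replicate 1 and at 2.63 and 2.62 in replicates 2 and 3. Hypoxia and glycolysis genes were lower for 14 of 16 (median −0.62, camera adjusted p = 1.84e-09), with the angiogenic factor Vegfa at −0.85 (SE 0.24). E2F targets, the genes of DNA replication, were higher for 29 of 30 members (median 0.30, camera adjusted p = 0.0025, against a median of 0.15 over all genes), but the test turned without inhibitor replicate 3 (median 0.21, adjusted p = 0.989). This call was lost with muscle and pancreas covariates (median 0.11, adjusted p = 0.453) and with sample quality weights (median 0.41, adjusted p = 0.0842). Pancreas transcripts moved with the immune lists. The pancreas list stood at 0.07, 0.09 and 5.57 in the inhibitor libraries and at −0.06, 7.04 and 8.89 in the combination libraries (9 of 9 members higher, median 3.40, camera adjusted p = 0.0289). T cell, CD8, B cell and dendritic cell lists were each higher in the 3 libraries with pancreas transcripts than in their group mates. Those group mates are the muscle-rich libraries, inhibitor replicates 1 and 2 and combination replicate 1, so both tissues mark the same split. T cell levels were 0.41, 0.85 and 1.09 in them. They were 1.58 in inhibitor replicate 3 and 2.80 and 2.88 in combination replicates 2 and 3. Antibody and muscle content thus partly coincide in this comparison. With muscle and pancreas covariates the medians of the T cell, CD8, B cell and dendritic cell lists fell to 0.62, 0.54, 0.42 and 0.33, and the calls held. limma called 0 genes, with 1556 unadjusted, and voom called 0, with 1633 unadjusted. Tubb3, a neuronal beta tubulin, had the lowest p of all genes (5.57 ± 0.28 RPKM with the inhibitor against 2.57 ± 0.16 in the combination, limma adjusted p = 0.618). The count was 1 without inhibitor replicate 3 and 16 without the 3 muscle-rich libraries, where it is the lone inhibitor sample. With sample quality weights, voom called 9510 genes, a setting that weighted inhibitor replicate 3 at 0.173 and combination replicate 1 at 0.257 and so set the 2 muscle-rich inhibitor libraries against combination replicates 2 and 3.

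Averaged over antibody, the inhibitor contrast holds 6 treated and 4 untreated libraries. Interferon response genes stood higher with the inhibitor and plasma cell genes lower, the latter mainly in the muscle-rich libraries. Genes of DNA replication, the process that the inhibitor's targets license, were not called. Camera called 15 lists, and none kept its call with an estimated correlation (smallest adjusted p = 0.917). Type I interferon genes were higher for 22 of 22 members (median log2 fold change 0.95, camera adjusted p = 6.11e-14), with Irf7 at 1.56 (SE 0.47) and Isg15 at 1.17 (SE 0.39), and MHC class I genes for 15 of 16 (median 0.27, camera adjusted p = 1.21e-04). Plasma cell and immunoglobulin genes were lower for 15 of 17 (median −0.97, camera adjusted p = 7.17e-06), as were liver genes (9 of 9, median −3.48), the latter not called by voom (adjusted p = 0.0557). Plasma cell levels were 3.88 and 4.78 in inhibitor replicates 1 and 2 and 4.83 in combination replicate 1, the muscle-rich libraries. The other treated libraries lay between 5.76 and 6.15, against 5.79 to 6.38 without the inhibitor (exact permutation p = 0.1 over all libraries). Liver transcripts stood out only in PBS replicate 2 and antibody replicate 2. The lymphoid structure chemokines were higher for 9 of 9 members (median 0.61, camera adjusted p = 0.0137). Their call was lost without inhibitor replicate 3 (median 0.12, adjusted p = 0.0705) or combination replicate 3 (median 0.46, adjusted p = 0.0537). It was also lost without PBS replicate 1 (median 0.39) or antibody replicate 2 (median 0.41), each of which leaves a lone sample in its group. Among cell cycle lists, the 30 E2F targets, which CDK4 and CDK6 release, did not pass (10 higher, median −0.05, camera adjusted p = 0.751). Mitosis genes were lower for 23 of 26 members (median −0.15, camera adjusted p = 0.0493) against a median of −0.05 over all genes. The mitosis call was lost without PBS replicate 2 (adjusted p = 0.664), without inhibitor replicate 2 (adjusted p = 0.322) or 3 (adjusted p = 0.525), without antibody replicate 1 (adjusted p = 0.337) and without combination replicate 1 (adjusted p = 0.121) or 2 (adjusted p = 0.0936). It was also lost with a pseudocount of 0.1 (median −0.17, adjusted p = 0.0661) and with voom (median −0.17, adjusted p = 0.068), where the median did not shrink. The median was smaller with median-ratio scaling (−0.10, adjusted p = 0.136) and quantile normalization (−0.079, adjusted p = 0.0767), and the call was lost. The same held for sample quality weights (−0.11, adjusted p = 0.549) and the muscle and pancreas covariates (−0.073, adjusted p = 0.0632). The proliferation marker Mki67 differed by −0.41 (SE 0.18, limma adjusted p = 0.966) and Top2a by −0.35 (SE 0.22), while E2f1 and the replication clamp gene Pcna lay at 0.22 (SE 0.20) and 0.10 (SE 0.16). The inhibitor's targets Cdk4 and Cdk6 stood at 17.9 ± 3.8 and 2.34 ± 1.0 RPKM with the inhibitor and 17.5 ± 3.3 and 2.51 ± 0.50 RPKM in PBS. limma called 0 genes, with 951 unadjusted, and voom called 0, with 960 unadjusted and 11 calls under sample quality weights. The lowest p on the lower side fell to Aldh1l1 (limma adjusted p = 0.160) and Pla2g4c, a phospholipase (log2 fold change −1.40, SE 0.16, limma adjusted p = 0.189). The count of genes was 104 without PBS replicate 1, 1 without antibody replicate 1 and 53 without the 3 muscle-rich libraries, where inhibitor replicate 3 alone stands for the inhibitor without antibody.

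**Figure D3:**
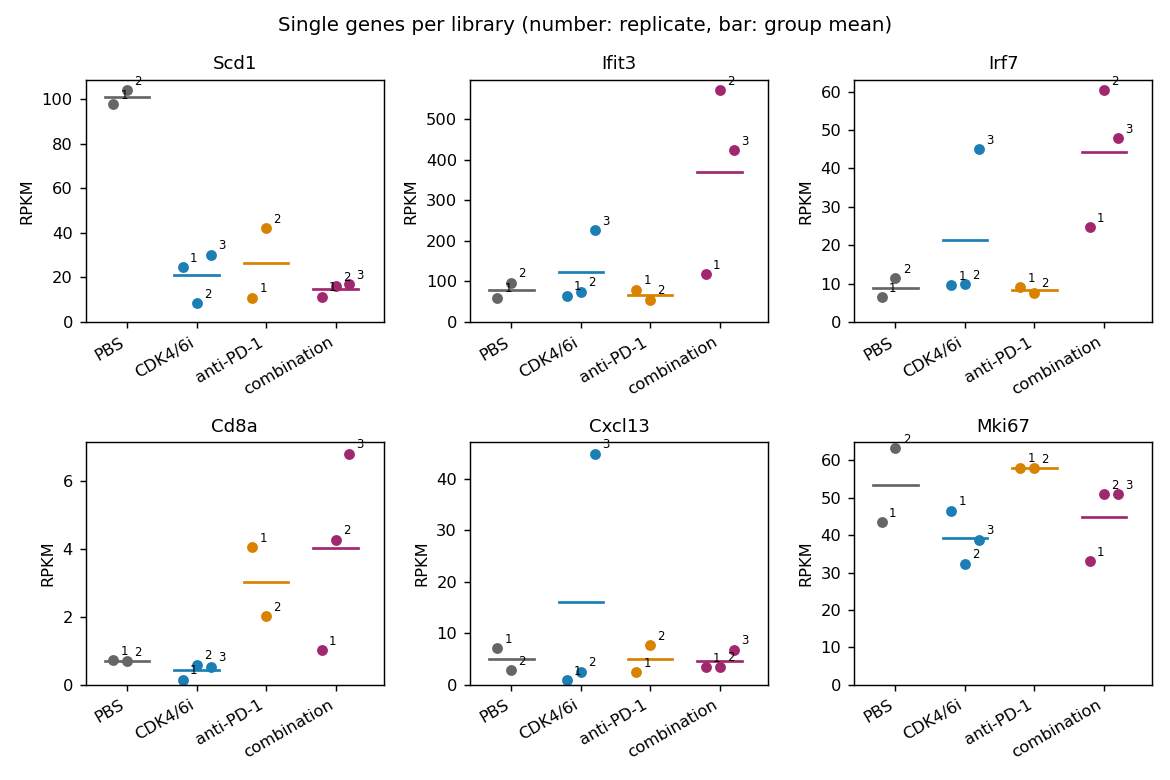
RPKM of 6 genes in each library, by treatment group on the x axis, 1 point per library numbered by replicate and a bar at the group mean. Scd1 lay at 97.7 and 103.9 RPKM in PBS and at most at 42.1 RPKM in the treated libraries, and Ifit3 reached 571 and 423 RPKM in combination replicates 2 and 3.

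A test that does not treat genes as replicates permuted the inhibitor labels within the antibody-treated and antibody-free samples, for each of 42 list levels. Its 100 arrangements allow a smallest two-sided exact permutation p of 0.01. A call over 42 lists therefore needs many lists at low p together, and the absence of calls says little. The intestine and liver lists reached 0.01, both lower with the inhibitor, and 0 lists passed after adjustment (adjusted p = 0.21 for each). The liver difference came from PBS replicate 2, at 7.72, and antibody replicate 2, at 4.67. All other libraries lay between −0.56 and −0.085, so that p rested on small gaps between low levels. The type I interferon list was 0.88 higher in log2 units (exact permutation p = 0.13, adjusted p = 0.91). The inhibitor's effect also differed with and without antibody for 9 lists by camera, type I interferon among them (interaction median 1.12, 22 of 22 higher, camera adjusted p = 0.0352), and for none with an estimated correlation (smallest adjusted p = 0.329). The interferon median was 0.69 without PBS replicate 2 (adjusted p = 0.657). It was 0.57 without the muscle-rich libraries (adjusted p = 0.216). There the lone inhibitor sample is replicate 3, which had the highest interferon level of its group (4.17 against 2.45 and 2.61). With all libraries kept, the call was lost with a pseudocount of 0.1 (median 1.19, adjusted p = 0.0563) and with the filter at 1 RPKM (median 1.12, adjusted p = 0.0523). The call was also lost, with medians of 0.92, 0.95, 0.90, 0.88 and 1.03, without inhibitor replicate 1 (adjusted p = 0.161) or 2 (adjusted p = 0.220), antibody replicate 2 (adjusted p = 0.543), and combination replicate 2 (adjusted p = 0.148) or 3 (adjusted p = 0.0835). For single genes the interaction gave 0 calls by limma, with 1089 unadjusted, and 0 by voom, with 1015 unadjusted. Across the 19368 genes, which are not independent replicates, the inhibitor's effects without and with antibody, from contrasts that share no library, correlated with Pearson's r = 0.222 and Spearman's rho = 0.306, and 45.2% of genes had the same sign. The correlation was −0.0205 without PBS replicate 2, 0.048 and 0.0455 without inhibitor replicates 1 and 2, and 0.425 without inhibitor replicate 3.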

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

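A camera test of the interaction picked out 9 lists whose inhibitor effect differed with and without the PD-1 antibody, and none of them passed with an estimated correlation. The tests of explanations were chosen after the results were seen, except for the other splits of the samples.

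Type I interferon genes had a higher inhibitor effect in the presence of the antibody (interaction median 1.12, adjusted p = 0.958 with an estimated correlation), the only 1 of the 9 lists on the higher side. The pancreas list differed by −7.24 (adjusted p = 0.329 with an estimated correlation), following the pancreas transcripts of the antibody libraries. Skin keratinocyte genes differed by −1.14 (adjusted p = 0.641), a list carried by antibody replicate 2, where these genes took 0.0476% of reads. Mast cell genes differed by −0.40 (adjusted p = 0.641), hypoxia and glycolysis genes by −0.20 (adjusted p = 0.641), fibroblast and matrix genes by −0.23 (adjusted p = 0.913), senescence-associated secretion by −0.22 (adjusted p = 0.958) and high endothelial venule genes by −0.15 (adjusted p = 0.329), each with an estimated correlation. The unfolded protein and integrated stress response list was called on the lower side with a median of 0.052 and a mean of −0.053 (adjusted p = 0.329). Camera tests a list against the other genes, and the median interaction over all genes was 0.33. A list median just above 0 can therefore be called lower, and the other medians here are to be read against 0.33 too.

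The first pattern weighed is the split of libraries by skeletal muscle transcripts. Of the 12 muscle genes, 11 had their 3 highest values in the same libraries, inhibitor replicates 1 and 2 and combination replicate 1. The read share of these same 12 genes had picked out those libraries. The count shows that the genes moved as a set. Muscle tissue carried into those samples would give this, but so would any other source of muscle RNA, so the count cannot tell the source. Against an effect of treatment stands the range within a group, 10.84 log2 units at its widest, where the largest difference between group means was 4.21. How the tumours were dissected is not given in the sources used here.

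The second pattern is the higher type I interferon list in the combination than in the antibody group. The muscle list stood at 7.85 in the combination and 3.64 in the antibody group, so dilution by muscle RNA would lower the interferon list in the combination, and its median of 2.13 with the muscle level as a covariate, against 1.502, decides nothing. More leukocyte RNA would leave no difference relative to Ptprc, the pan-leukocyte marker CD45, yet the list mean relative to Ptprc was 1.43 higher in the combination (standard error 0.20). Against PBS, the difference relative to Ptprc was 0.42 (standard error 0.22) out of 1.37 without the reference, so leukocyte content cannot be told apart from a response per cell there, with 2 PBS libraries. A treatment effect on interferon signalling stays open as a hypothesis.

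The third pattern is Scd1, lower in all 8 treated libraries than in both PBS libraries. Fat in PBS replicate 1 and liver in PBS replicate 2 are candidate sources of Scd1 transcripts. A non-negative sum of Adipoq and Alb levels fitted on the 8 treated libraries predicted 168 RPKM for PBS replicate 1 (observed 97.7) and 89.2 RPKM for PBS replicate 2 (observed 103.9), so the lowest predicted value was 0.858 of the observed one. Refits that left out 1 library predicted from 42.2 to 17409 RPKM for PBS replicate 2, far beyond the fitted range. Host tissue and treatment therefore cannot be told apart for Scd1, because each PBS library carries 1 of the 2 tissues.

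For chance, the splits of the 6 inhibitor and combination libraries are too few, 10, for a share under 0.05. The real grouping called 0 genes, a number that any split must reach, and the highest other split called 6074. That split put inhibitor replicates 1 and 2 with combination replicate 1, a structure of the samples that follows the muscle transcripts. For lists, 2 of the 10 splits called as many as the real 23, and the highest other called 24. For the averaged inhibitor effect the real count was 0 genes, which each of the 100 arrangements within antibody strata must reach, with up to 2858. The gene counts therefore decide nothing about chance. As many lists as the real 15 were called by 44 of the 100 arrangements, with up to 27, so chance cannot be excluded for the number of lists called.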

How the results depend on the processing

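Tests with voom, with quality weights, with tissue covariates and without the 3 muscle-rich libraries were chosen after the data were seen. The alternative with DESeq2 was not run, because the deposited unit was RPKM. Across the alternatives that kept all or several libraries, named genes kept direction and side of the threshold in 1920 comparisons, gained a call in 65 and turned in 13. The main fit called 0 genes in every contrast, so no named gene could lose a call. Many were also named for their low p, so a kept direction follows in part from that choice. These gene counts are therefore no measure of stability. Lists discussed kept their call in 687, lost it in 53 and turned in 8. With 1 library left out, where a lone sample is assumed to vary like the other groups, named genes were unchanged in 1452 comparisons and gained a call in 18, and lists were unchanged in 492, lost their call in 40 and turned in 8. The permutation of list levels gave 0 under each alternative run, a result nearly fixed in advance. With a smallest p of 0.01, a call over 42 lists needs many lists at low p together. Leaving out a library raises that smallest p. The cause was not tested except where stated.

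Where limma called 0 genes, a pseudocount of 1 gave 1 gene for the antibody against PBS and 1 for the combination against the antibody. Without a filter, which adds genes near 0, the counts were 8 for the inhibitor, 23 for the antibody and 7 for the combination against PBS, and 15 for the combination against the antibody. Quantile normalization gave 1 gene for the antibody against PBS and 15 lists for the interaction, and median-ratio scaling gave 14 lists for the interaction. Without trend and robust moderation 2 genes were called for the antibody against PBS and 2 for the combination against the antibody. With only the PBS and antibody libraries 66 genes were called. With the replicate number as a block, 1 gene was called for the antibody against PBS and 1 gene and 7 lists for the averaged inhibitor effect, and the correlation of effects was 0.4998. List calls lost under it were MHC class I (median 0.12, adjusted p = 0.114) and the lymphoid chemokine and mitosis lists (adjusted p = 0.391 for each) for the averaged effect, and the lymphoid chemokines for the inhibitor against PBS (median −0.26, adjusted p = 0.197), the B cell list for the combination against PBS (median 0.26, adjusted p = 0.0649) and the mitosis (median −0.088, adjusted p = 0.0829) and interferon gamma lists (median 0.41, adjusted p = 0.225) for the combination against the antibody. The numbers do not pair the samples: 13 pairs of equal number had a median correlation across genes of 0.018 after group means were removed, from −0.449 to 0.620.

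With voom 8 lists were called for the averaged inhibitor effect. With quality weights voom called 100 genes for the combination against the antibody, 9510 against the inhibitor, 11 genes for the averaged effect and 18 lists for the interaction. With the muscle covariate 1 gene was called for the antibody against PBS and 15 lists for the interaction, and the B cell (median −0.025), interferon gamma (0.019) and lymphoid chemokine calls (0.011) for the antibody against PBS were lost.

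With the muscle and pancreas covariates, 11 lists were called for the antibody against PBS, 10 for the combination against PBS, 23 lists and 1 gene for the combination against the antibody and 21 lists for the interaction. Results that turned for the antibody against PBS were Cd8b1 (−0.96), Cd8a (−0.91), Cd3d (−0.91), Cd5 (−0.74), Pdcd1 (−1.54), Glycam1 (−0.23), Cd79b (−1.41) and Cxcl9 (−1.05), and the B cell (−1.73), T cell (−1.17), CD8 and cytotoxic (−1.195), interferon gamma (−1.38), checkpoint (−1.35) and lymphoid structure chemokine lists (−1.33). For the combination against PBS they were Ccl4 (−0.016), Ms4a1 (−0.18), Cd22 (−0.44), the B cell list (−0.37) and the E2F list (−0.20). The combination's T cell (median −0.0015), MHC class II (0.064), checkpoint (−0.093), lymphoid organisation (−0.21), immediate early (−0.66) and pancreas calls (0.076) against PBS were lost, as were the pancreas calls for the antibody against PBS (−0.12) and the combination against the antibody (0.23). The correlation of effects was −0.175. The pancreas list level was at least 10.19 in the antibody libraries and at most 0.17 in PBS, so this fit removes much of that contrast by construction. The lost pancreas calls were fixed in advance, because that list was adjusted for its own level.

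Without the 3 muscle-rich libraries inhibitor replicate 3 is the lone sample of the inhibitor alone, assumed to vary like the other groups, so every contrast with that group rests on it. The counts of genes were 37 for the inhibitor, 50 for the antibody and 1 for the combination against PBS, 1 for the combination against the antibody, 16 against the inhibitor, 53 for the averaged effect and 3 for the interaction. The counts of lists were 22 for the inhibitor against PBS, 20 for the combination against the antibody and 29 for the averaged effect. E2f1 (−0.13) and Pcna (−0.046) turned for the averaged effect, and the correlation was −0.025. The plasma cell (median −0.47), fatty acid (−0.18) and liver calls (−4.45) for the inhibitor against PBS and the interferon call of the interaction (0.57) were lost.

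With 1 library left out, the gene counts ran from 0 to 117 for the inhibitor, 0 to 39 for the antibody and 0 to 94 for the combination against PBS, 0 to 6 for the combination against the antibody, 0 to 1 against the inhibitor and 0 to 104 for the averaged effect. The counts of lists ran from 8 to 17, 14 to 27, 14 to 27, 9 to 19, 17 to 27, 8 to 16 and 8 to 16 in the order of the contrasts, the interaction last. The correlation of effects ran from −0.0205 to 0.425. Medians of lists whose test turned ran from −2.79 to 0.43 for immediate early genes and from −0.078 to 0.34 for E2F targets in the combination against PBS, and from 0.21 to 0.49 for E2F targets in the combination against the inhibitor. For liver genes with the inhibitor they ran from −9.12 to −0.0021. For fatty acid and sterol genes they ran from −0.92 to −0.090 with the inhibitor, from −0.82 to 0.0067 with the antibody and from −0.68 to 0.14 with the combination. For interferon gamma genes in the combination against the antibody they ran from 0.38 to 1.28.

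Depth limits the values of low genes most.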

Other observations

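The phospholipase gene Pla2g4c separated treated from untreated libraries in these data. It lay between 4.06 and 5.76 RPKM in the 4 libraries without inhibitor and between 1.23 and 2.36 RPKM in the 6 with it, and it did not pass the adjustment over all genes.

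Inhibitor replicate 3 stood apart from the other libraries in inflammatory secretion. Cxcl1 reached 519 RPKM there, Il6 20.9 RPKM and Timp1, an inhibitor of matrix proteases, 430 RPKM. In the other 9 libraries these genes stayed at or below 23.4, 1.56 and 66.8 RPKM. Cxcl13 was also highest in that library, and the neutrophil list level was 3.11 against at most 2.25 elsewhere. Cdkn2a, which encodes an inhibitor of CDK4 and CDK6, stood at 0.524 ± 0.11 RPKM with the inhibitor alone (SD, n = 3) and 1.59 ± 0.044 RPKM in PBS (SD, n = 2), without passing (limma adjusted p = 0.844). In the presence of the antibody it was not lower with the inhibitor. It stood at 1.28 ± 0.51 RPKM in the combination and 0.995 ± 0.14 RPKM with the antibody alone, a log2 fold change of 0.21 (SE 0.27). These genes were singled out after their values were seen.

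A hypothesis of this re-analysis, formed and tested on the same data, is that the interferon response per leukocyte is higher with the inhibitor. The tests in this part were chosen after the result was seen, except the change of reference. The type I interferon list relative to Ptprc was higher in each inhibitor-treated library than in each untreated library of the same antibody status. It stood at 0.64 to 1.09 with the inhibitor against −0.13 and 0.08 in PBS, and at 0.06 to 0.74 in the combination against −1.07 and −1.01 with the antibody. The mean difference was 1.15 log2 units, with a two-sided exact permutation p of 0.01, the smallest that the 100 arrangements can give, and an adjusted p of 0.21 over 42 lists. With other references, 2 of 3 kept a p of 0.05 or less, the macrophage and T cell lists (exact permutation p = 0.01 for each), while the epithelial and mesothelial list gave an exact permutation p of 0.09. The macrophage and T cell lists measure leukocytes as Ptprc does, so they speak only against the choice of that 1 gene. Without a reference the difference was 0.88 (exact permutation p = 0.13). In inhibitor replicates 1 and 2 the interferon list itself stood at 2.45 and 2.61, against 2.41 and 3.17 in PBS, so their ratio was high through low Ptprc, at 2.07 and 2.98 RPKM. Interferon genes active outside leukocytes would give the same ratio, and a response beyond leukocyte number stays open. The lymphoid structure chemokines relative to Ptprc also reached 0.01 (difference 0.78), the interferon gamma list had an exact permutation p of 0.02 (difference 0.57), and plasma cell genes lay 0.58 lower (difference −0.58, exact permutation p = 0.04). None of the 42 lists passed after adjustment, which with 100 arrangements needs many lists at low p together.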
